A study of Rattus norvegicus with 36 samples.

How the data were processed

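Bulk RNA sequencing was done on primary alveolar macrophages from male F344/HanZtmRj rats. Per the labels' protocols, the cells were kept for 5 days in DMEM with 10% fetal bovine serum and exposed for 4 days to a control, non-overload or overload condition of Printex90 (carbon black), G1-1, G3-1 or Bayertitan (titanium dioxides). RNA was extracted with an RNeasy kit and treated with DNase, and libraries were made from 150 ng of total RNA with the KAPA RNA HyperPrep kit with RiboErase, which removes ribosomal RNA. Salmon, FastQC and MultiQC and the rat build Rnor_6.0 are named in the submitters' processing notes. Their versions, the annotation, the step from transcripts to genes and the particle doses behind overload and non-overload are not given in the sources used.

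The deposited table holds estimated counts per gene, not scaled to a common library size, for 23487 gene symbols and 36 libraries. Of its values 47.7% are not whole numbers. Of its IDs 133 end in a suffix that marks a repeated symbol, and these were kept as separate entries. Estimated counts divide the reads of near-identical copies by a model, so values of multigene families such as the RT1 genes, ferritins and metallothioneins are uncertain, as are those of overlapping and antisense genes. Gene positions were not used here. Column totals ran from 22274300 to 37131500. Mitochondrially encoded genes held 1.99 to 3.13% and the 20 highest genes 13.1 to 16.8% of a library's total, and TMM factors ran from 0.934 to 1.07. All 36 columns were matched to samples by name, and no 2 libraries of a group were close enough to be duplicates. Over the 36 pairs of libraries within groups, the chi-square per gene was 7.05 to 54.8, where sampling noise alone gives about 1.

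Counts were rounded to whole numbers, filtered with edgeR's filterByExpr by group (14498 genes left) and normalised by TMM. Expression is given in the counts-per-million unit (CPM) on those library sizes. The ranges and figure of Cd68, Lyz2, Col3a1, Epcam and Krt8 and the Col3a1 limit use CPM on column totals, without the TMM factor. A single edgeR quasi-likelihood model (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with a mean for each of the 12 groups and 24 residual degrees of freedom was fitted to all 36 libraries. Contrasts gave overload and non-overload against the particle's own controls, overload against non-overload, the means of these effects over the 4 particles, and differences of overload effects between particles, and an F test compared the 4 control groups. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors of log2 fold changes were taken from the fit, and errors of CPM values are standard deviations of 3 libraries.

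There were 34 gene lists with 761 listings, of which 735 had an entry in the table and 660 were tested. On more than 1 list stood 35 genes. The lists covered inflammation, antioxidant, stress and hypoxia responses, lysosome, lipid and metal handling, antigen presentation, fibrosis, p53, cell cycle, respiration, ribosomes and macrophage identity. Others held markers of monocytes, dendritic cells, neutrophils, lymphocytes, eosinophils, erythroid cells, fibroblasts, endothelium and epithelium. Lists with at least 3 tested genes, 33 of them, were tested with fry (limma) on voom-weighted log2 CPM. Its directional p asks whether the genes of a list move on balance one way and does not compare the list with other genes. Precision weights give each gene its own residual space, so residuals were turned to a common basis before the correlation of genes was taken. This step was added after the data were seen, because without it the values moved with rounding error. Among the calls by fry it ended 1, dendritic cell markers with G1-1 overload, and changed no other in the fit without covariates. Counts of list calls with covariates or replicate blocks also changed. The p-values were adjusted over the 297 tests of 33 lists in 9 comparisons, and camera with a preset and an estimated correlation was run as an alternative. Over that family 26 list results passed by fry and 9 by camera with an estimated correlation.

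Genes named in the text were chosen by a fixed rule. It took the 5 largest rises and falls past the test per overload comparison and the 3 per non-overload comparison, and the smallest p-values for averages and differences. The largest changes needed a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups. It added 2 to 4 members of each list that passed and a set of fixed genes. The fixed genes are given for the average and, for single particles, where they passed there or their effects differed between particles. This reading of the rule was set after the results had been seen. Of the genes picked by the rule 3 are not reported here, and no other genes took their place. Counts of picked genes leave them out. The groups, comparisons, tests, gene lists, naming rule and first set of alternative settings were fixed before the data were examined. Where a group had no counts, a floor of 3 counts over the group was used, and ratios of small counts carry exact 95% intervals. These intervals cover counting error only.

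Alternatives were DESeq2 size factors in edgeR, no filter on low counts, the DESeq2 Wald test (DESeq2 1.42.0) and a fit of the 9 libraries of 1 particle. Further ones were the replicate number as a block within each particle, a minimum change of 2-fold and leaving out each library in turn. Others were added after seeing the data. These were a covariate for the mean log2 CPM of 5 fibroblast markers, of 6 epithelial markers or both, a fit without the 15 libraries with Col3a1 above 10 CPM, a robust quasi-likelihood fit, and the Printex90 effect against each titanium dioxide alone. Where a fit left 1 library in a group, that library was assumed to vary like the other groups. Scores of other cell types were compared by two-sided exact permutation tests, which with 3 libraries against 3 give no p below 0.1. The pipeline was tested on simulated counts for Printex90 overload with 200 changed genes among 14498. A list of 25 further genes was raised 1.3-fold. It recovered 47.8% of 67 genes changed 1.5-fold, 64.2% of 67 changed 2-fold and 92.4% of 66 changed 4-fold. Of the calls 6 of 158 (3.80%) were unchanged genes. The simulated libraries did not differ in fibroblast or epithelial content, so this rate does not cover calls that arise from such differences.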

Results

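Alveolar macrophages clear inhaled particles from the air spaces. RNA was sequenced from those of male F344/HanZtmRj rats after 4 days of exposure in culture to 1 of 4 particles. Printex90 is a carbon black, and G1-1, G3-1 and Bayertitan are titanium dioxides. Each particle was given at 2 loadings, named non-overload and overload in the labels, and had control cultures of its own. This made 12 groups of 3 libraries, 36 in all. The series was set up to compare the response of alveolar macrophages to particle overload between species, of which the rat cells are described here. Of the 23487 listed genes 14498 were tested. Cd68, a lysosomal membrane protein of macrophages, lay between 508 and 835 CPM, the counts-per-million unit used here (on column totals for these ranges and those of the next paragraph), and Lyz2, which encodes lysozyme, between 9950.0 and 16324 CPM in the 36 libraries. The p-values rest on libraries labelled biological replicates, and the labels do not say whether these came from separate animals.

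The libraries also held transcripts of other lung cells. Col3a1, a collagen gene of fibroblasts, was at 13.1 to 651 CPM in 15 libraries and at no more than 1 count in the other 21. The 15 libraries were control replicates 1 and 2 and non-overload replicate 1 of Printex90, and control replicate 1, non-overload replicate 2 and overload replicate 1 of G1-1. The others were control replicate 3, non-overload replicates 1 and 3 and overload replicates 2 and 3 of G3-1, and control replicate 3, non-overload replicates 2 and 3 and overload replicate 1 of Bayertitan. The epithelial genes Epcam and Krt8 were present in every library, at 39.1 to 195 and 306 to 663 CPM. The mean log2 expression of 6 epithelial markers was lower in overload than in control libraries by a mean difference of -0.42 over the 4 particles (two-sided exact permutation test within particles, p = 0.0223, n = 12 per arm). Within a particle the difference was -0.58 (exact p = 0.2) for Printex90, 0.27 (exact p = 0.6) for G1-1, -0.58 (exact p = 0.1) for G3-1 and -0.79 (exact p = 0.1) for Bayertitan. An exact test of 3 libraries against 3 can give no p below 0.1.

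**Figure D1:**
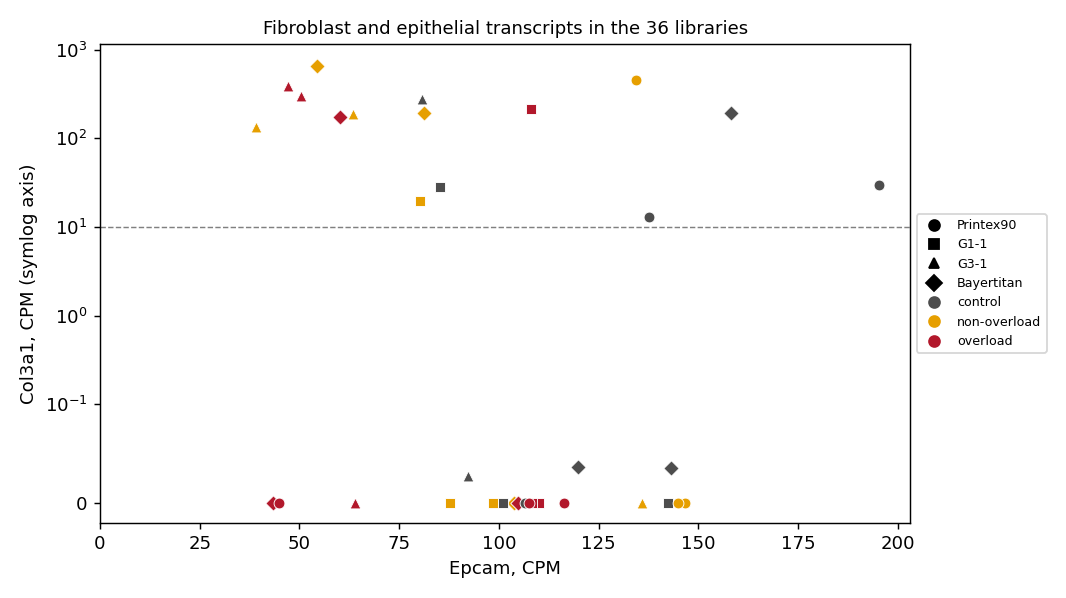
Col3a1 (vertical symlog axis, CPM), a fibroblast gene, against Epcam (horizontal axis, CPM), an epithelial gene, with marker shape by particle and colour by loading. The dashed line marks 10 CPM of Col3a1: 15 libraries lie above it, and the other 21 sit at or near 0.

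The carbon black at its overload loading was compared with its own controls. Targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor, were lower after Printex90 overload. Cyp1b1, a cytochrome P450 enzyme induced through this receptor, was at 68.1, 72.8 and 46.5 CPM in the controls, the last of which had no fibroblast signal, and at 0.0514 ± 0.0587 CPM after overload (SD, n = 3). Over the group it went from 5300 to 4 counts, a ratio of 1195 with a 95% counting interval from 466 to 4386. Cyp1a1, a related enzyme, had 152 counts in the controls and 0 after overload, at least 45.7-fold lower against a floor of 3 counts over the group. Tiparp, an ADP-ribosyltransferase that limits the receptor, fell from 51.8 ± 4.91 to 29.8 ± 1.52 CPM (log2 fold change -0.80, SE 0.099, adjusted p = 1.32e-05). The receptor's repressor Ahrr fell from 2.07 ± 0.506 to 0.220 ± 0.0991 CPM, and the quinone reductase Nqo1 fell from 53.8 ± 2.24 to 34.7 ± 4.99 CPM. Aldh3a1, an aldehyde dehydrogenase gene, fell from 76 to 3 counts over the group (ratio 22.8, counting interval 7.52 to 113). In total 6 of the 10 tested members fell and 0 rose by edgeR, with 6 lower and 0 higher adjusted over the list alone. Without the libraries with fibroblast signal, which left 1 control, Cyp1b1 and Ahrr passed. The other 4 did not, among them Tiparp at -0.66 and Nqo1 at -0.64 on the log2 scale. The list as a whole was lower (fry, median log2 fold change -0.72, adjusted p = 5.06e-05; adjusted p = 0.028 with an estimated correlation).

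Inflammatory mediators and antigen presentation genes were also lower with Printex90 overload. The chemokine Cxcl6 fell from 167 ± 25.8 to 50.1 ± 15.4 CPM (log2 fold change -1.74, SE 0.34, adjusted p = 0.00261; SD, n = 3 per group). Il1a, which encodes interleukin 1 alpha, fell from 47.7 ± 8.84 to 24.8 ± 1.58 CPM (adjusted p = 0.00373). The granulocyte growth factor gene Csf3 fell from 6.40 ± 1.22 to 2.59 ± 0.248 CPM. The chemokine genes Ccl20 and Cxcl2 and Il1b fell by 1.72, 0.78 and 1.07 on the log2 scale. Of 28 tested cytokine and chemokine genes 9 fell and 0 rose (11 fell and 2 rose adjusted over the list alone), with a list test of adjusted p = 0.00464 but adjusted p = 0.312 with an estimated correlation. Cd74, the invariant chain of class II major histocompatibility complexes, fell from 141 ± 14.5 to 67.7 ± 5.97 CPM (log2 fold change -1.06, SE 0.12, adjusted p = 6.11e-06). Ciita, the transcriptional activator of these genes, fell by 1.47 on the log2 scale. The class II genes RT1.Bb and RT1.Da fell by 1.18 and 1.08. Those values are uncertain because reads of this multigene family can be divided among near copies. In this group 8 of 18 tested genes fell and 1, B2m, rose (the same numbers adjusted over the list alone; adjusted p = 0.00464, adjusted p = 0.437 with an estimated correlation). Stab1, a scavenger receptor, fell from 16.3 ± 3.41 to 2.94 ± 0.602 CPM (adjusted p = 1.03e-05). The airway genes Scgb1a1 and Muc4, with log2 fold changes of -3.40 and -2.66, were among the 5 largest falls with Clca4l at -2.77. The epithelial marker mean of these libraries differed by -0.58 and the fibroblast marker mean by -3.01 from the controls.

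Genes of lysosomal acidification, lipid handling, iron storage and glycolysis were higher with Printex90 overload. Of 25 tested genes for the vacuolar proton pump and targets of TFEB-family factors 15 rose and 0 fell (21 adjusted over the list alone; adjusted p = 0.0314, adjusted p = 0.537 with an estimated correlation). The gene for the pump subunit Atp6v0d2 rose from 186 ± 16.7 to 265 ± 48.3 CPM (SD, n = 3 per group), and the nutrient-sensing genes Fnip2 and Rragc by 0.50 and 0.34 on the log2 scale. The fatty acid binding protein gene Fabp5 rose (log2 fold change 0.66, SE 0.082, adjusted p = 1.47e-05), and the desaturase gene Scd2 rose from 857 ± 78.7 to 1217 ± 132 CPM. Their lipid efflux and storage list of 22 had 9 higher and 1, Fasn, lower (12 and 1 adjusted over the list alone; adjusted p = 0.00676, adjusted p = 0.438 with an estimated correlation). Lgals3, Ctsd and Vim rose by 0.41, 0.37 and 0.43. In all 11 of 18 genes of lipid-associated macrophages rose (12 and 1 lower adjusted over the list alone; adjusted p = 0.0139, adjusted p = 0.515 with an estimated correlation). The ferritin genes Fth1 and Ftl1 rose by 0.50 and 0.44 and the metallothionein gene Mt1 by 0.87 on the log2 scale. They were among 6 of 16 metal and iron genes that were higher (7 and 1 lower adjusted over the list alone; adjusted p = 0.0212, adjusted p = 0.537 with an estimated correlation). Reads of the ferritin and metallothionein genes can be shared with near-identical copies, which makes their values uncertain. The autophagy receptor genes Optn and Tax1bp1 rose by 0.58 and 0.37. On the autophagy list 6 of 25 genes were higher (7 and 1 lower adjusted over the list alone; adjusted p = 0.0349, adjusted p = 0.563 with an estimated correlation). The lactate exporter gene Slc16a3 rose from 135 ± 19.5 to 208 ± 21.3 CPM and the mitophagy receptor gene Bnip3 rose from 73.0 ± 11.2 to 141 ± 23.7 CPM. Of 29 hypoxia and glycolysis genes 12 were higher and 0 lower (17 and 1 adjusted over the list alone; adjusted p = 0.0071, adjusted p = 0.437 with an estimated correlation). Among the 5 largest rises were Gcgr (1.15), F13a1 (1.12), Mmp8 (0.97) and Drc3 (0.96), each log2.

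By edgeR's quasi-likelihood test 1158 genes changed with Printex90 overload, 746 higher and 412 lower. At least 2-fold changes were seen in 14 that rose and 141 that fell. For each of the 50 genes picked by the naming rule, Hmox1, Gpnmb, Mmp12 and Cdkn1a included, all 3 overload libraries lay beyond all 3 controls. Chance gives 10% of genes that order, and the rule required it of the largest changes. The antioxidant gene Hmox1 rose by 0.31, the glycoprotein gene Gpnmb by 0.38 and the elastase gene Mmp12 by 0.40, while Cdkn1a fell by 0.43, all on the log2 scale. The count was 280 without control replicate 1 (32 of the 50 picked genes kept), and 749 without control replicate 2 (48 kept). Without overload replicate 1 it was 2234 (50 kept) and without overload replicate 2 it was 178 (29 kept). Nqo1 and Muc4 did not pass without overload replicate 3. The count was 165 in a fit of the 9 Printex90 libraries alone (23 kept), 563 with the epithelial marker mean as a covariate (44 kept) and 53 without the libraries with fibroblast signal, which left 1 control (11 kept). Hmox1, Gpnmb, Mmp12, Cdkn1a, Nqo1, Fth1 and Ctsd were lost in both the first and the last of these fits.

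**Figure D2:**
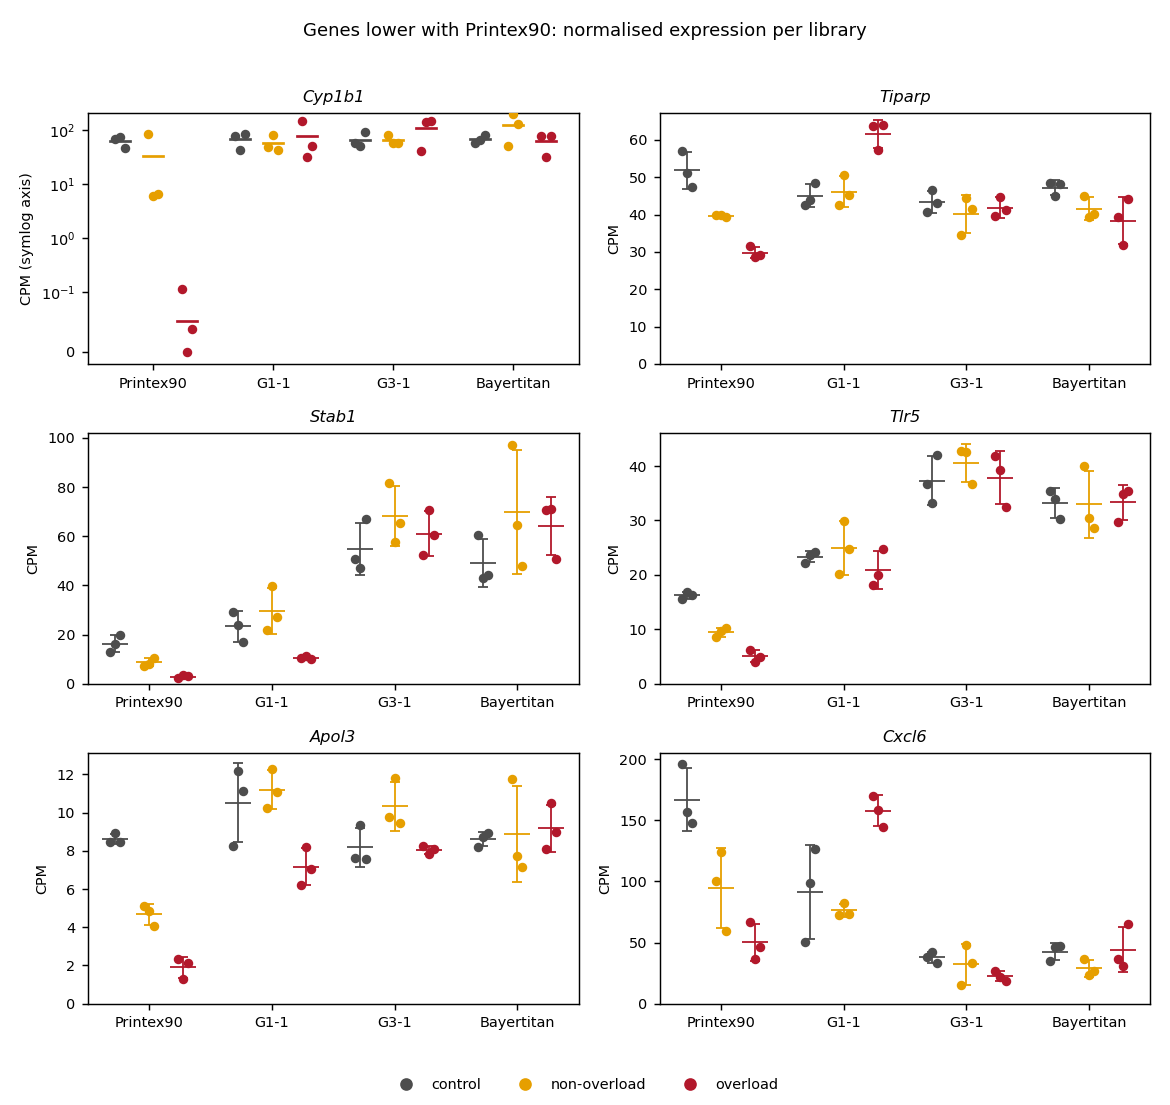
Normalised expression (vertical axes, CPM; symlog for Cyp1b1) of 6 genes by particle (horizontal axes) and loading (colour), with the mean of 3 and, on linear axes, a bar of 1 SD. Cyp1b1 fell from 62.5 to 0.0514 CPM and Stab1 from 16.3 to 2.94 CPM between the Printex90 control and overload libraries.

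For the titanium dioxide G1-1, glucose uptake and glycolysis genes rose at overload. Slc2a1, the glucose transporter GLUT1, rose from 309 ± 29.3 to 594 ± 44.1 CPM (log2 fold change 0.94, SE 0.071, adjusted p = 3.31e-09; SD, n = 3 per group). The hexokinase gene Hk2 rose from 510.4 ± 20.4 to 997 ± 86.8 CPM (log2 fold change 0.97, SE 0.083, adjusted p = 3.49e-08). Pfkfb3, a regulator of glycolytic flux, rose from 210.0 ± 0.736 to 328 ± 17.4 CPM. Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, rose from 4.68 ± 1.06 to 20.7 ± 6.70 CPM and the vasodilator peptide gene Adm rose from 4.78 ± 1.33 to 19.3 ± 11.6 CPM. Of 29 hypoxia and glycolysis genes 20 rose and 0 fell (23 adjusted over the list alone; fry, median log2 fold change 0.54, adjusted p = 4.07e-06; adjusted p = 0.0102 with an estimated correlation). Txnip, which restrains glucose uptake, fell from 185 ± 44.5 to 59.2 ± 14.4 CPM (log2 fold change -1.65, SE 0.17, adjusted p = 5.49e-07). Genes of the integrated stress response rose too, with Trib3 going from 7.69 ± 1.56 to 21.5 ± 3.51 CPM (log2 fold change 1.49, SE 0.20, adjusted p = 1.85e-05). Ddit3, Atf4 and Mthfd2 rose by 0.65, 0.45 and 0.68 on the log2 scale. In that list 10 of 28 genes rose and 0 fell (12 and 1 adjusted over the list alone; adjusted p = 0.00247, adjusted p = 0.138 with an estimated correlation).

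Tissue remodelling genes rose with G1-1 overload, and class II genes fell. The transglutaminase gene Tgm2 rose from 573 ± 73.9 to 963 ± 98.8 CPM (SD, n = 3 per group), and the arginase gene Arg1 rose from 153 ± 20.4 to 218 ± 15.8 CPM. The urokinase gene Plau and the collagenase gene Mmp8 rose by 0.40 and 0.78 on the log2 scale. Of 28 fibrosis and remodelling mediators 9 were higher and 0 lower (11 adjusted over the list alone; adjusted p = 5.06e-05, adjusted p = 0.0107 with an estimated correlation). Lcn2, Nos2 and Stc2 were among the 5 largest rises with log2 fold changes of 2.28 ± 0.48, 2.44 ± 0.68 and 2.08 ± 0.61 (SE). Cd74 fell from 162 ± 7.59 to 97.7 ± 8.17 CPM, and RT1.Bb, RT1.Da and RT1.Db1 fell by 0.97, 0.81 and 0.90. Among 18 antigen presentation genes 5 were lower and 0 higher (7 and 1 adjusted over the list alone; adjusted p = 0.0071, adjusted p = 0.409 with an estimated correlation). The complement genes C1qa, C1qb and C1qc fell by 0.80, 0.92 and 1.32. The chemokine receptor gene Cx3cr1 went from 69 to 10 counts over the group (ratio 6.62, counting interval 3.39 to 14.4). These genes belong to 15 monocyte and recruited macrophage markers, of which 6 were lower and 1, F13a1, higher (7 and 1 adjusted over the list alone; adjusted p = 0.0435, adjusted p = 0.537 with an estimated correlation). Other large falls were in Fcrl2 (-2.17), Kazald1 (-1.21) and Stab1 (-1.14).

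With G1-1 overload 727 genes changed by edgeR, 334 higher and 393 lower, with 30 rises and 18 falls of at least 2-fold. Cxcl2, Mt1 and Pdgfa, the last a growth factor for fibroblasts, rose by 0.62, 0.60 and 0.27, and Il1b fell by 0.83 on the log2 scale. All 3 overload libraries lay beyond all 3 controls for each of the 33 called genes picked by the naming rule. The epithelial marker mean differed by 0.27 and the fibroblast marker mean by 0.86 between overload and control. The count was 347 without control replicate 1, 400 without control replicate 2, 412 without overload replicate 1 and 345 without overload replicate 3, with 25, 26, 27 and 27 of the 33 genes kept. It rose to 1120 with the epithelial covariate and to 1910 with both marker covariates, and was 139 without the libraries with fibroblast signal, where 21 of the 33 were kept. Among the genes lost there were Lcn2, Nos2, Stc2, Adm, Plau, Atf4, C1qb, Stab1, Cxcl2, Il1b, Mt1 and Pdgfa. Il1b and Mt1 did not pass in any of the 6 fits without 1 library, and Cxcl2 and Pdgfa did not pass with the replicate number as a block.

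**Figure D3:**
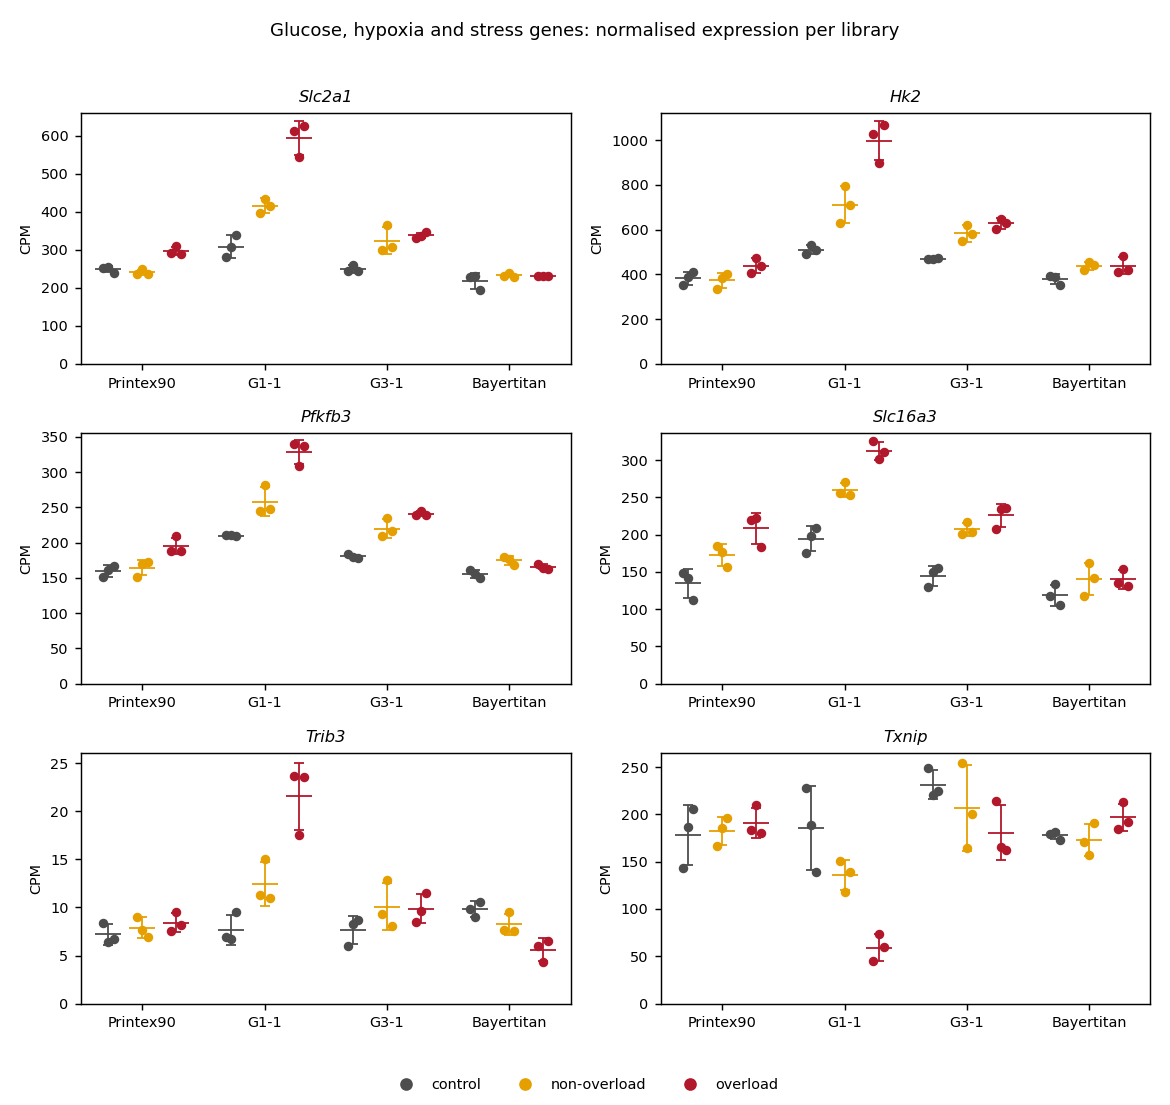
Normalised expression (vertical axes, CPM) of 6 genes of glucose use and stress by particle (horizontal axes) and loading (colour), with 1 point per library, the mean of 3 and a bar of 1 SD. In G1-1 overload Slc2a1 reached 594 CPM against 309 in its controls, while Txnip went from 185 to 59.2 CPM.

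G3-1 overload changed fewer genes, with rises on the hypoxia and glycolysis list. Pfkfb3 rose from 180.5 ± 2.52 to 241 ± 3.36 CPM (log2 fold change 0.42, SE 0.058, adjusted p = 0.00125; SD, n = 3 per group), and Slc2a1 rose from 249.9 ± 10.0 to 338 ± 7.23 CPM (log2 fold change 0.44, SE 0.071, adjusted p = 0.00663). Slc16a3 rose from 145 ± 13.3 to 226 ± 15.9 CPM and Bnip3 rose from 77.7 ± 13.6 to 149 ± 13.7 CPM. The enolase gene Eno2, the adenylate kinase gene Ak4 and the prolyl hydroxylase gene Egln1 rose by 0.62, 0.54 and 0.61 on the log2 scale. Of the 29 hypoxia and glycolysis genes 8 rose and 0 fell (19 adjusted over the list alone; adjusted p = 0.000615, adjusted p = 0.0247 with an estimated correlation). By edgeR 17 genes changed, 13 higher and 4 lower. For the 8 of them named by the fixed rule, Ehd1 (-0.39) included, all 3 overload libraries lay beyond all 3 controls. The other 3 that fell, Tbcb, Pllp and Bex4, are named after their values were seen. Tbcb was listed at 263 counts in the controls and 0 after overload. It was also listed at 0 in libraries of other groups (6 of 36 in all), so no fold is given. Pllp had 34 and 2 counts (ratio 14.5, counting interval 3.72 to 125) and Bex4 66 and 7 (ratio 8.04, counting interval 3.69 to 20.8). The count was 1 without control replicate 1, 11 without control replicate 2, 60 without overload replicate 1, 6 without overload replicate 2 and 1 without overload replicate 3. It was 0 in a fit of the 9 G3-1 libraries alone and without the libraries with fibroblast signal. The fibroblast marker mean differed by 3.50 and the epithelial marker mean by -0.58 from the controls, and the count was 14 with the fibroblast covariate and 24 with the epithelial one. DESeq2 called 77 genes, and 1770 passed at an unadjusted p under 0.05.

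Genes of lipid-laden macrophages, the proton pump and several chemokines were higher in the Bayertitan overload libraries, where the epithelial marker mean was lower and no gene passed with that mean as a covariate. The lipoprotein lipase gene Lpl rose from 2554 ± 420.1 to 3866 ± 622 CPM (SD, n = 3 per group). Fabp4, Cd9, Trem2 and Spp1 rose by 0.72, 0.45, 0.49 and 0.37 on the log2 scale. Of 18 lipid-associated macrophage genes 14 rose and 0 fell (15 adjusted over the list alone; adjusted p = 0.0071, adjusted p = 0.515 with an estimated correlation). Of 22 lipid efflux and storage genes 6 rose (8 adjusted over the list alone; adjusted p = 0.0349, adjusted p = 0.58 with an estimated correlation). Atp6v0d2 rose from 156 ± 20.5 to 225 ± 27.3 CPM (log2 fold change 0.53, SE 0.11, adjusted p = 0.0188). Among 25 pump and TFEB-family genes 15 were higher (20 adjusted over the list alone; adjusted p = 0.039, adjusted p = 0.58 with an estimated correlation). The chemokine genes Ccl3 and Ccl4, the growth factor gene Csf1 and Il18 rose by 0.47, 0.46, 0.43 and 0.27. They were the only ones higher of 28 cytokine genes (6 adjusted over the list alone; adjusted p = 0.022, adjusted p = 0.537 with an estimated correlation). Of 8 neutrophil markers 2 rose, the metalloproteinase genes Mmp8 and Mmp9, by 0.70 and 0.60 (4 adjusted over the list alone; adjusted p = 0.0447, adjusted p = 0.642 with an estimated correlation). The largest falls were in Timp3 (-2.12), Akap5 (-2.00), Clic5 (-1.87), Ckmt1 (-1.77) and Ephb6 (-1.76). The largest rises were in Best1 (1.03), Dcn (1.01), Slc9a9 (0.90), Cd5l (0.85) and F13a1 (0.84). Dcn is also on the list of fibroblast markers.

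By edgeR 1426 genes changed with Bayertitan overload, 832 higher and 594 lower, with 11 rises and 146 falls of at least 2-fold. Mmp12, Gpnmb and Hmox1 rose by 0.51, 0.36 and 0.33 on the log2 scale. For all 31 called genes picked by the naming rule the 3 overload libraries lay beyond the 3 controls. The epithelial marker mean differed by -0.79 on the log2 scale in the overload libraries, and with it as a covariate 0 genes passed by edgeR. The count was 848 without control replicate 1, 762 without control replicate 2, and 0 without control replicate 3, with 24, 23 and 0 of the 31 genes kept. It was 277 without overload replicate 1, 0 without overload replicate 2 and 2319 without overload replicate 3, with 15, 0 and 30 kept. It was also 0 in a fit of the 9 Bayertitan libraries alone and without the libraries with fibroblast signal, against 2103 by DESeq2 and 4106 genes at an unadjusted p under 0.05.

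At the non-overload loading, genes passed with G1-1 only, 5 of 9 of them from the hypoxia and glycolysis list. Hk2 rose from 510.4 ± 20.4 to 711 ± 82.7 CPM (log2 fold change 0.48, SE 0.082, adjusted p = 0.0173; SD, n = 3 per group), and Slc2a1 rose from 309 ± 29.3 to 416 ± 19.0 CPM. Ero1a, Kdm3a and Pfkfb3, the others on that list, rose by 0.47, 0.37 and 0.30 on the log2 scale. The genes outside the list that passed by edgeR were Eno2 (0.55), Mettl9 (0.53), Cdr2 (0.42) and Elmsan1 (0.36). Pfkfb3, Cdr2 and Elmsan1 are named after their values were seen. Of the 29 hypoxia and glycolysis genes 5 rose (16 adjusted over the list alone; adjusted p = 0.00461, adjusted p = 0.028 with an estimated correlation). The count was 0 without control replicate 1, without control replicate 2, without non-overload replicate 2 or without non-overload replicate 3, 2 without control replicate 3 and 0 without the libraries with fibroblast signal, against 21 by DESeq2. With the other 3 particles 0 genes passed by edgeR. For Printex90 non-overload 628 genes had an unadjusted p under 0.05 and DESeq2 called 11, for G3-1 782 and 11, and for Bayertitan 2352 and 38. Without non-overload replicate 1 the Bayertitan count was 88.

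Some gene lists moved together at this loading with no member past the gene test. For Printex90 non-overload, Tiparp was at 39.7 ± 0.362 against 51.8 ± 4.91 CPM (adjusted p = 0.607) and Cyp1a1 at 0.185 ± 0.109 against 1.84 ± 1.08 CPM (SD, n = 3 per group). The aryl hydrocarbon receptor list was lower (0 of 10 genes passed, 2 adjusted over the list alone; median -0.21, adjusted p = 0.003, adjusted p = 0.00667 with an estimated correlation). Nqo1 and Aldh3a1 had log2 fold changes of -0.32 and -2.01 there. Cyp1b1 was at 6.22 and 6.63 CPM (column totals) in non-overload replicates 2 and 3, but at 89.3 in replicate 1, with fibroblast signal. Control replicate 3, without it, had 47.1. For G3-1 non-overload the hypoxia and glycolysis list was higher (0 of 29 passed, 16 adjusted over the list alone; median 0.31, adjusted p = 0.00609, adjusted p = 0.0301 with an estimated correlation). Slc2a1, Egln1, Slc16a3 and Pfkfb3 had log2 fold changes of 0.38, 0.58, 0.51 and 0.29. The list of 15 monocyte and recruited macrophage markers was higher in the same libraries (0 passed, 1 adjusted over the list alone; adjusted p = 0.022, adjusted p = 0.0741 with an estimated correlation). F13a1 had a log2 fold change of 0.91 there, and C1qa, C1qb and C1qc had 0.38, 0.32 and 0.32.

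**Figure D4:**
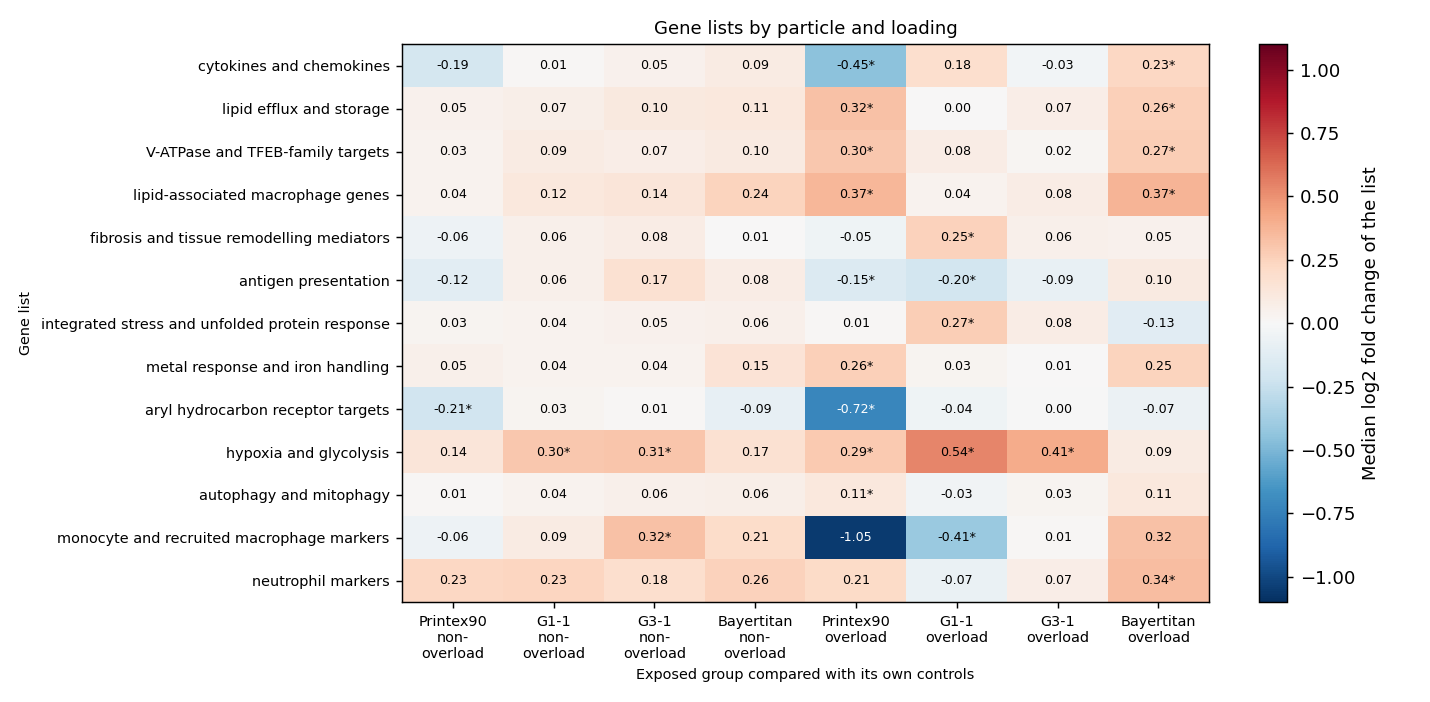
Median log2 fold change (colour and number) of each gene list (vertical axis) that passed in at least 1 of the 8 comparisons with controls (horizontal axis), starred where fry's adjusted p was under 0.05. The hypoxia and glycolysis list had a median of 0.54 in G1-1 overload and 0.41 in G3-1 overload, and the aryl hydrocarbon receptor list one of -0.72 in Printex90 overload.

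The 2 loadings of each particle were then compared directly. With Printex90 the class II gene Cd74 was lower at overload than at non-overload (67.7 ± 5.97 against 109 ± 3.18 CPM, SD, n = 3; log2 fold change -0.69, adjusted p = 0.00507). So were Stab1 (-1.56), Tlr5, a receptor for flagellin (-0.89), Apol3 (-1.28), the lipoxygenase gene Alox5 (-0.81) and Tiparp (-0.41), while Fabp5 (0.48) and Mmp8 (0.65) were higher. By edgeR 230 genes differed, 183 higher and 47 lower. Without 1 library the count was 19 (non-overload replicate 1), 50 (non-overload replicate 2), 1078 (overload replicate 1) or 11 (overload replicate 2). It was 0 in the 9 Printex90 libraries alone (2984 genes at an unadjusted p under 0.05 in the fit of all libraries), and DESeq2 called 885. With G1-1, Slc2a1 (594 ± 44.1 against 416 ± 19.0 CPM; log2 fold change 0.51, adjusted p = 9.70e-05), Hk2 (0.49), Pfkfb3 (0.35) and Trib3 (0.79) were higher at overload. Txnip (-1.20), C1qc (-1.44), Fcrl2 (-2.26) and Cd74 (-0.78) were lower. There 282 genes differed, 85 higher and 197 lower. The number was 106, 151 and 89 without non-overload replicates 1, 2 and 3, 69 without overload replicate 1 and 83 without overload replicate 3, and 471 by DESeq2. For G3-1 and Bayertitan 0 genes differed by edgeR, with 920 and 927 genes at an unadjusted p under 0.05 and 3 and 2 called by DESeq2. Leaving out G3-1 overload replicate 1 gave 26.

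Averaged over the 4 particles, overload raised glycolysis, lysosome and lipid genes and lowered antigen presentation and p53 genes by the tests of single genes and by fry. None of these lists passed by camera with an estimated correlation, which compares a list with other genes. The epithelial marker mean differed by -0.42 in the same average. Of 29 hypoxia and glycolysis genes 24 rose and 0 fell (24 and 0 adjusted over the list alone). Log2 changes were 0.43 ± 0.035 for Slc2a1, 0.45 ± 0.041 for Hk2, 0.52 ± 0.043 for Ero1a and 0.36 ± 0.029 for Pfkfb3 (SE, n = 12 per arm). Of 32 lysosomal genes 22 rose and 2 fell (24 and 2 adjusted over the list alone). The protease genes Ctsb (0.28 ± 0.045) and Ctsd (0.27 ± 0.041) were higher and Ctsc (-0.26 ± 0.044) and Ctsh lower. In addition 20 of 25 pump and TFEB-family genes rose (22 adjusted over the list alone), such as Atp6v0d2 (0.33 ± 0.055), Fnip2 (0.42 ± 0.051), Flcn (0.20 ± 0.039) and Rragc (0.22 ± 0.041). In the lipid lists Fabp5 (0.37 ± 0.041), Scd2 (0.46 ± 0.040), Srebf1 (0.31 ± 0.039), Plin2 (0.32 ± 0.057) and Vim (0.41 ± 0.049) rose. Of 20 genes of alveolar macrophage identity, with the same numbers adjusted over the list alone, 14 rose, Krt79 (0.40 ± 0.072) and Bhlhe40 (0.20 ± 0.036) among them, and 2 fell, Csf2rb (-0.40 ± 0.065) and Siglec5. The metalloproteinase genes Mmp8 and Mmp9 rose by 0.72 ± 0.072 and 0.50 ± 0.067, and the stress genes Psat1, Ddit3 and Atf3 by 0.36 ± 0.038, 0.36 ± 0.049 and 0.27 ± 0.052. The class II genes RT1.Bb and Cd74 fell by 0.63 and 0.53, and C1qb and C1qc by 0.75 and 0.79 on the log2 scale, though C1qc was at 24.7 ± 3.05 and 24.9 ± 2.06 CPM in Bayertitan control and overload libraries (SD, n = 3). Of 22 p53 and DNA damage genes 11 fell (13 adjusted over the list alone) and 1, Gdf15 (0.35 ± 0.072), rose. Among those that fell were Aen (-0.31 ± 0.058), Cdkn1a (-0.27 ± 0.055) and Bax (-0.15 ± 0.033).

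Epithelial genes were lower in the same average. Of 13 lung epithelial markers 7 were lower (10 adjusted over the list alone), Aqp5 (-2.33 ± 0.51), Scgb1a1 (-1.96 ± 0.41), Ager (-0.85 ± 0.18) and Nkx2.1 (-0.67 ± 0.16) among them, and 1, Lamp3, higher. Areg, Dpp4 and Irf8 fell by 1.02, 0.88 and 0.22 on the log2 scale. Among the genes fixed in advance, Hmox1 (0.27 ± 0.044), Atp6v0d2, Mt1 (0.44 ± 0.089), Mmp12 (0.27 ± 0.054) and Gpnmb (0.23 ± 0.051) rose. Il1b (-0.53 ± 0.12), Nqo1 (-0.24 ± 0.083), Cdkn1a, Cyp1a1 and Cyp1b1 fell. The fitted values of Cyp1a1 and Cyp1b1 (-2.64 ± 0.43 and -2.33 ± 0.54) depend on the prior count and are no bound. Values that did not pass were 0.10 ± 0.039 for Pdgfa, 0.10 ± 0.042 for Tgfb1, 0.12 ± 0.059 for Abca1, 0.099 ± 0.056 for Spp1 and 0.12 ± 0.088 for Mki67. Nor did -0.092 ± 0.082 for Cxcl2 and 0.049 ± 0.083 for Ccl2 pass. Tnf was listed at 0 in G3-1 control replicate 1, G3-1 overload replicate 2 and Bayertitan control replicate 1 and at 9.87 to 20.9 CPM in the other 33 libraries. Its mean difference (0.24 ± 0.47) rests on estimates that can fail at such a value. By edgeR 3484 genes changed, 1731 higher and 1753 lower, 22 and 94 of them by at least 2-fold. Leaving out any 1 library gave between 2697 and 3991, and of the named genes only Nqo1 (adjusted p = 0.0367) was lost. The smallest adjusted p-values belonged to Slc2a1, Ero1a, Pfkfb3, Nav1 (0.62 ± 0.049), Hsdl2 (0.47 ± 0.040) and Eno2 (0.58 ± 0.050) among rises. Among falls they belonged to Sh3bp1 (-0.28 ± 0.028), RT1.Bb, Cd74, C1qb, C1qc and Dhrs1 (-0.34 ± 0.040). The count was 1626 with the epithelial covariate, where Aldh3a1, Tiparp and Dpp4 no longer passed. It was 1110 without the libraries with fibroblast signal, where Gpnmb, Il1b, Cyp1a1, Tiparp, Dpp4, Ager, Aqp5, Nkx2.1, Scgb1a1, Fth1, Slc39a8, Atp5f1b, Aen, Bax and Gdf15 did not pass.

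The list tests of the mean over particles were adjusted together with those of the mean non-overload effect. Lists past the test were hypoxia and glycolysis (6.90e-08), lipid-associated macrophage genes (0.000641), antigen presentation (0.00106), lipid efflux and storage (0.00122), fibrosis and remodelling (0.00122), aryl hydrocarbon receptor targets (0.00122), p53 (0.00184), neutrophil markers (0.00138), and pump and TFEB-family genes (0.00265), each with fry's adjusted p. Others past it were dendritic cell markers (0.0042), lung epithelial markers (0.00802), the integrated stress response (0.00971), alveolar macrophage identity (0.0097), lysosome (0.0175), metal and iron (0.0229), autophagy (0.0229) and the respiratory chain (0.0405). With an estimated correlation none of them passed, at adjusted p = 0.0676 for hypoxia and glycolysis and from 0.475 to 0.546 for the others. Of 16 metal and iron genes 6 rose and 3 fell (8 and 3 adjusted over the list alone), with Fth1 at 0.24 ± 0.055 and the zinc importer gene Slc39a8 at -0.40 ± 0.091. Of 25 autophagy genes 8 rose and 2 fell (9 and 2), with Optn at 0.39 ± 0.055 and Wipi2 at -0.14 ± 0.028. Of 32 respiratory chain genes 13 rose and 0 fell (14 and 0), with Sdhc at 0.14 ± 0.030 and Ndufb3 at 0.14 ± 0.035. For the other lists past the test, the genes higher and lower, with those adjusted over the list alone in brackets, were 15 and 1 (15 and 1) of 18 lipid-associated macrophage genes, 10 and 2 (10 and 4) of 22 lipid efflux and storage genes and 10 and 6 (14 and 6) of 28 fibrosis and tissue remodelling mediators. They were 2 and 8 (2 and 8) of 18 antigen presentation genes, 0 and 5 (1 and 6) of 10 aryl hydrocarbon receptor targets, 8 and 1 (8 and 2) of 28 integrated stress genes, 2 and 0 (2 and 0) of 8 neutrophil markers and 0 and 2 (0 and 3) of 6 dendritic cell markers. The antigen presentation, aryl hydrocarbon receptor, p53, dendritic cell and epithelial lists were lower by fry and the rest higher. For lists that did not pass, the numbers of genes higher and lower are given in the same form. They were 5 and 2 (5 and 2) of 28 cytokine and chemokine genes (adjusted p = 0.792), 7 and 2 (7 and 2) of 22 NF-kB targets and inflammatory enzymes (0.362) and 5 and 5 (5 and 5) of 20 NRF2 antioxidant genes (0.792). The next were 6 and 1 (6 and 1) of 24 cholesterol genes (0.151), 5 and 3 (5 and 4) of 21 phagocytosis and pattern recognition receptors (0.629) and 1 and 0 (0 and 0) of 28 type I interferon genes (0.709). Last were 1 and 1 (1 and 1) of 34 cell cycle genes (0.911), 1 and 7 (1 and 7) of 16 heat shock genes (0.0592), 5 and 7 (6 and 8) of 23 inflammasome and cell death genes (0.911) and 3 and 4 (3 and 4) of 15 monocyte and recruited macrophage markers (0.12). In the same form, markers of other cells had 1 and 0 (1 and 0) of 7 T and NK cell markers (Cd2 higher; 0.362), 0 and 1 (0 and 1) of 4 B cell markers (Pou2af1 lower; 0.423) and 3 and 0 (3 and 0) of 14 fibroblast and endothelial markers (Dcn, Cdh5 and Tie1 higher; 0.29). The remaining groups had 0 and 0 (0 and 0) of 3 erythroid markers (0.854), 0 and 0 (0 and 0) of 13 mitochondrially encoded genes (0.878) and 0 and 5 (0 and 5) of 33 cytosolic ribosomal proteins (0.191). The eosinophil and mast cell list, with 1 tested gene of 13, was not tested.

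In the mean non-overload effect over the 4 particles 6 of the lists passed, none of them with an estimated correlation. They were hypoxia and glycolysis (17 of 29 genes higher, 25 adjusted over the list alone; adjusted p = 2.64e-05, 0.0676), lipid-associated macrophage genes (4 of 18 genes higher, 14 adjusted over the list alone; adjusted p = 0.0134, 0.475) and p53 and DNA damage (3 of 22 genes lower, 9 adjusted over the list alone; adjusted p = 0.0154, 0.475). With them came neutrophil markers (2 of 8 genes higher, 2 adjusted over the list alone; adjusted p = 0.0148, 0.475), monocyte and recruited macrophage markers (1 of 15 genes higher, 1 adjusted over the list alone; adjusted p = 0.0405, 0.48) and aryl hydrocarbon receptor targets (0 of 10 genes lower, 3 adjusted over the list alone; adjusted p = 0.0466, 0.475). The second p in each bracket is that with an estimated correlation. Eno2 (0.43), Ero1a (0.31), Hk2 (0.24), Slc2a1 (0.21) and Pfkfb3 (0.20) rose on the log2 scale. So did Mmp9 (0.30), Mmp8 (0.28), Vim (0.26), Plin2 (0.22), Fabp5 (0.17) and F13a1 (0.89), while Cdkn1a (-0.21) and Aen (-0.23) fell. Adjusted p ran from 4.67e-05 for Eno2 to 0.0388 for Cdkn1a, with n = 12 per arm. These genes were taken from those named for overload after the values were seen. The marker means for fibroblasts and epithelium were 1.56 and -0.26 on the log2 scale in the same average (exact p = 0.347 and 0.156). By edgeR 399 genes changed, 225 higher and 174 lower, against 938 by DESeq2. The count was 193 and 213 without G3-1 control replicates 1 and 2 and 236, 1338 and 170 without G3-1 non-overload replicates 1, 2 and 3. It was 147 without Bayertitan control replicate 3 and 757, 156 and 240 without Bayertitan non-overload replicates 1, 2 and 3. It was 228 and 159 without G1-1 control replicates 2 and 3 and 179 and 170 without G1-1 non-overload replicates 2 and 3. It was 151 and 199 without Printex90 control replicates 1 and 2 and 193 and 184 without Printex90 non-overload replicates 1 and 2. It was 247 without a filter on low counts, 879 with both marker covariates and 1 without the libraries with fibroblast signal.

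To ask which responses were particular to a particle, the overload effects were subtracted from each other. The overload changes of Apol3 and Tlr5 were lower with Printex90 than in the mean of the titanium dioxides, by log2 differences of -2.00 ± 0.21 and -1.63 ± 0.18 (SE; adjusted p = 8.79e-06 for both). So were those of Alox5 (-1.08 ± 0.14), Tiparp (-0.83 ± 0.11), Stab1 (-2.28 ± 0.33) and the inflammatory genes Cxcl6 (-1.77 ± 0.39), Csf3 (-1.55 ± 0.32), Il1a (-1.08 ± 0.22) and Cxcl2 (-0.92 ± 0.19). Part of this came from higher values with G1-1 overload than in its controls, at 158 ± 12.7 against 91.6 ± 38.6 CPM for Cxcl6, 52.1 ± 2.91 against 35.7 ± 11.9 for Il1a and 61.6 ± 3.75 against 45.1 ± 3.15 for Tiparp. The inflammatory genes also had their highest control means with Printex90. Cxcl6 was at 167 CPM there against 91.6, 37.8 and 42.6 in the controls of G1-1, G3-1 and Bayertitan. In the same order Il1a was at 47.7 against 35.7, 21.0 and 22.5 and Csf3 at 6.40 against 4.78, 2.04 and 2.48. Cxcl2 was at 31.3 against 17.0, 15.2 and 15.5. After Printex90 overload Cxcl6, Il1a, Csf3 and Cxcl2 were at 50.1, 24.8, 2.59 and 18.2 CPM. Cxcl6, Csf3 and Il1a passed against G1-1 alone but not against G3-1 (adjusted p = 0.453, 0.294 and 0.332) or Bayertitan (adjusted p = 0.203, 0.115 and 0.331). Cxcl2 did not pass against G3-1 (adjusted p = 0.727), Tiparp against Bayertitan (0.261), or Alox5 and Stab1 against G1-1 (0.0783 and 0.0904). Usp15 did not pass against G3-1 (0.245) or Bayertitan (0.522), nor Sapcd2 against G1-1 (0.0585) or Bayertitan (0.743), and neither passed with the fibroblast covariate. Cyp1b1 had 76.2 ± 61.5, 109 ± 59.1 and 62.5 ± 26.2 CPM in G1-1, G3-1 and Bayertitan overload against 0.0514 ± 0.0587 with Printex90 (SD, n = 3; adjusted p = 0.000637). Cyp1a1 differed likewise (adjusted p = 0.00318), while Ahrr did not pass (adjusted p = 0.0864). By edgeR 32 genes differed, 30 lower and 2, Sapcd2 (0.51 ± 0.11) and Usp15 (0.24 ± 0.052), higher with Printex90. The aryl hydrocarbon receptor list was lower (3 of 10 genes, 5 adjusted over the list alone; adjusted p = 0.000139, adjusted p = 0.00473 with an estimated correlation). So was the cytokine list (4 of 28 genes, 14 adjusted over the list alone; adjusted p = 0.000926, adjusted p = 0.00913 with an estimated correlation). The count was 18 without Printex90 control replicate 3 and 20 without overload replicate 2 or 3 of Printex90. Cyp1a1, Cyp1b1, Tiparp, Alox5, Apol3, Stab1 and Tlr5 passed in every fit without 1 library. In such fits the adjusted p reached 0.116 for Cxcl2 (Printex90 overload replicate 1), 0.141 for Csf3 and 0.207 for Il1a (control replicate 1). It reached 0.262, 0.23 and 0.284 for Cxcl6, Sapcd2 and Usp15 (overload replicate 2). Without the libraries with fibroblast signal the count was 12 and only Cyp1b1, Apol3, Stab1 and Tlr5 of the 13 named genes passed. With the replicate number as a block Cxcl2, Csf3, Cxcl6, Il1a, Sapcd2 and Usp15 did not pass (count 28). DESeq2 called 77, and the count was 141 against G1-1 alone and 21 against G3-1 alone.

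Among the titanium dioxides G1-1 differed from the others. The overload change of Slc2a1 was higher with G1-1 than with Bayertitan (log2 difference 0.85 ± 0.10 SE, adjusted p = 2.26e-05). So was that of Kdm3a, a hypoxia-induced demethylase (0.80 ± 0.095), while Txnip (-1.79 ± 0.24) and Polr2k, a small subunit of RNA polymerases (-1.09 ± 0.12), had lower ones. By edgeR 703 genes differed, 204 higher and 499 lower with G1-1. The count was 412 and 228 without Bayertitan control replicates 1 and 3 and 446 and 211 without Bayertitan overload replicates 1 and 2. It was 169, 259 and 1157 without G1-1 control replicates 1, 2 and 3 and 233 and 354 without G1-1 overload replicates 1 and 3. The count was 144 with the epithelial covariate and 7 without the libraries with fibroblast signal. All 4 named genes passed in each of those fits. The epithelial marker mean differed from the controls by 0.27 with G1-1 and -0.79 with Bayertitan overload. Against G3-1, the insulin receptor substrate gene Irs2 (0.60 ± 0.099) and Sema4b (0.65 ± 0.12) had higher changes and Polr2k (-0.93 ± 0.12) and Rbis, a ribosome biogenesis factor (-0.68 ± 0.083), lower ones with G1-1. In all 31 genes differed, 11 higher and 20 lower. That count was 14, 19 and 19 without G3-1 control replicates 1, 2 and 3 and 50, 13 and 10 without G3-1 overload replicates 1, 2 and 3. It was 8, 15 and 59 without G1-1 control replicates 1, 2 and 3 and 11 and 8 without G1-1 overload replicates 1 and 3. Sema4b no longer passed without control replicate 1 of either particle, without overload replicates 2 or 3 of G3-1 or without overload replicate 3 of G1-1, nor with the replicate number as a block or the epithelial covariate. The count was 0 without the libraries with fibroblast signal, which ended the calls of all 4 genes named here. Between G3-1 and Bayertitan 0 genes differed by edgeR (1277 at an unadjusted p under 0.05, 6 by DESeq2), 1 without G3-1 control replicate 3 and 3 without G3-1 overload replicate 1. The fixed genes Cxcl2, Cyp1a1 and Cyp1b1, whose effects differed between particles, had overload effects of -0.55 ± 0.17, -0.53 ± 0.60 and 0.72 ± 0.67 with G3-1. With Bayertitan they were 0.34 ± 0.16, -0.21 ± 0.58 and -0.12 ± 0.67, and with G1-1 those of Cyp1a1 and Cyp1b1 were -1.13 ± 0.61 and 0.16 ± 0.67. None of these passed.

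The overload calls of different particles, which have separate controls, shared more genes in most pairs than independent lists of the same sizes would. Genes that rose were shared by Printex90 and Bayertitan in 329 against 42.8 expected and by Printex90 and G1-1 in 118 against 17.2. They were shared by G1-1 and Bayertitan in 64 against 19.2, by G1-1 and G3-1 in 13 against 0.299 and by Printex90 and G3-1 in 11 against 0.669. Genes that fell were shared by Printex90 and Bayertitan in 98 against 16.9 and by Printex90 and G1-1 in 52 against 11.2, but by G1-1 and Bayertitan in 6 against 16.1. Of the genes that rose with G1-1 7 fell with Bayertitan, and of those that fell with G1-1 23 rose. The epithelial marker mean was lower in both Printex90 (-0.58) and Bayertitan overload (-0.79), the pair that shared most, and the comparison with independent lists does not allow for that. Over all tested genes, passing or not, the overload log2 fold changes had correlations of -0.136 for Printex90 and G1-1, -0.0428 for Printex90 and G3-1 and 0.222 for Printex90 and Bayertitan. They were 0.302 for G1-1 and G3-1, 0.0934 for G1-1 and Bayertitan and 0.326 for G3-1 and Bayertitan.

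The 4 control groups, which received no particle, differed from each other. The scavenger receptor gene Stab1 was at 16.3 ± 3.41 and 23.3 ± 6.24 CPM in the controls of Printex90 and G1-1 and at 54.9 ± 10.5 and 49.2 ± 9.89 in those of G3-1 and Bayertitan (SD, n = 3). C1qb was at 11.2 ± 0.260, 11.1 ± 0.948, 21.1 ± 1.15 and 24.7 ± 1.95 CPM in the same order. Cxcl6 ran the other way, at 167 ± 25.8 and 91.6 ± 38.6 against 37.8 ± 4.30 and 42.6 ± 6.82 CPM. These 3 genes were chosen after their values were seen. By an edgeR test over the 4 groups 810 genes differed. In pairs 1058 differed between the controls of Printex90 and G3-1, 335 between G1-1 and Bayertitan, and 111 between Printex90 and Bayertitan. The others were 50 between Printex90 and G1-1, 49 between G1-1 and G3-1 and 44 between G3-1 and Bayertitan. The overall count was 411 and 478 without G3-1 control replicates 1 and 3, 430 without Bayertitan control replicate 3 and 452 without G1-1 control replicate 2. It was 312 and 470 without Printex90 control replicates 1 and 2 and 41 without the libraries with fibroblast signal. As none was given, no particle can cause these differences. A batch tied to the particle could, but the labels name none. Differences between particles rest on effects within each particle.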

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

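The tests of lower aryl hydrocarbon receptor activity, of a response graded by the G1-1 loading and in libraries without fibroblast signal were chosen only after the result was seen.

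Overload effects that differed between particles drew attention, each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment of the difference itself. Between Printex90 and the mean of the 3 titanium dioxides 32 genes differed. The log2 differences were -0.92 for Cxcl2, -1.55 for Csf3, -1.77 for Cxcl6, -1.08 for Il1a and -1.08 for Alox5. They were -2.00 for Apol3, -2.28 for Stab1, -1.63 for Tlr5, -0.83 for Tiparp, 0.51 for Sapcd2 and 0.24 for Usp15. Against single titanium dioxides Cxcl6, Csf3 and Il1a passed for G1-1 only. Their control means were highest with Printex90. The fitted differences of Cyp1a1 (-8.08) and Cyp1b1 (-10.32) depend on the prior count and are no bound. By fry the cytokine list (median -0.67) and the aryl hydrocarbon receptor list (median -0.68) were lower with Printex90. Of 100 drawn regroupings of the libraries, the real one included, 8 gave as many genes, and the highest other gave 1217 against 32. Each regrouping exchanges overload and control libraries within every particle, so a change shared by the particles can turn into a difference between them. High counts can therefore arise without a difference of the real effects, and the share cannot decide whether chance made the count. Chance is not excluded.

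Between G1-1 and G3-1 31 genes differed, with log2 differences of 0.60 for Irs2, 0.65 for Sema4b, -0.93 for Polr2k and -0.68 for Rbis. In 11 of 100 regroupings as many genes passed, and the highest other gave 364. By the same limit chance is neither shown nor excluded. Between G1-1 and Bayertitan 703 genes differed, with 0.80 for Kdm3a, 0.85 for Slc2a1, -1.09 for Polr2k and -1.79 for Txnip. There the highest other regrouping gave 427, and only the real one of 100 gave as many. The regroupings remove the overload effects of both particles, so this cannot exclude chance for a difference between them.

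The first pattern was the fall of aryl hydrocarbon receptor targets with Printex90, in libraries whose fibroblast marker mean was -3.01 and epithelial marker mean -0.58 against the controls. Fewer fibroblasts are argued against as the whole cause, since with the fibroblast covariate the 6 fallen members had a median log2 fold change of -3.62 and all 6 passed, against -3.73 without it, a median that stays the same with Cyp1a1 and Cyp1b1 at their floor values; in the libraries without fibroblast signal (1 control, 3 overload) it was -3.71, with 2 passing. Fewer epithelial cells are argued against likewise, with a median of -3.72 and 5 of 6 passing with the epithelial covariate. Lower activity of the receptor in cells given carbon black stays open: of Ahrr, Tiparp, Nqo1 and Aldh3a1 all 4 fell, but these are among the 6 genes that define the pattern, so their fall decides nothing. Less ligand in the medium and binding of ligand by carbon black stay open too and were not tested.

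The second pattern was the rise of hypoxia and glycolysis genes with G1-1. A different epithelial and fibroblast content is argued against as the whole cause, since with both covariates the median log2 fold change of the list was 0.47 with 22 of 29 genes passing, against 0.54 without them. A response graded by the loading may be a hypothesis, as the list was also higher in overload than in non-overload (median 0.21, past the test by fry). Less oxygen at the cells under a dense particle layer and activation of the same genes without it stay open, because no oxygen or protein was measured here.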

How the results depend on the processing

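The covariates, the fits without libraries with fibroblast signal, the robust fit and the single reference particles were chosen only after the result was seen. DESeq2 size factors and the robust fit left all 19 counts of changed genes within 1.5 times those reported, and so did Bayertitan as the sole reference for Printex90. For named genes and lists DESeq2 size factors kept the call of 251 results and ended 2, DESeq2 kept 246 and added 7, and the fits without fibroblast signal kept 124 and ended 124. The cause of the moves was not tested, though fits with fewer libraries have fewer degrees of freedom and a fold minimum removes small changes. Depth limits genes at a few counts, such as Cyp1a1 after Printex90 overload. No alternative planned was left out, apart from the fit of 9 libraries for comparisons between particles.

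With DESeq2 the count was 77 for G3-1 overload, 11, 21, 11 and 38 for non-overload with Printex90, G1-1, G3-1 and Bayertitan and 885, 471, 3 and 2 for the loadings of Printex90, G1-1, G3-1 and Bayertitan. It was 938 for mean non-overload, 77 for Printex90 minus titanium dioxides and 124 for G1-1 minus G3-1 there. It was 1097 for G1-1 minus Bayertitan, 6 for G3-1 minus Bayertitan and 1473 for the control groups there. With the 9 libraries of the particle alone the count was 165, 0 and 0 for overload with Printex90, G3-1 and Bayertitan, 2 for G1-1 non-overload and 0 for Printex90 between loadings. Without a filter on low counts the count was 837 for Bayertitan overload, 145 for Printex90 between loadings and 247 for mean non-overload. It was 16 for G1-1 minus G3-1 and 466 for G1-1 minus Bayertitan there. With a change of at least 2-fold as well the count was 155, 48, 3 and 157 for overload with Printex90, G1-1, G3-1 and Bayertitan, 0 for G1-1 non-overload and 13 and 20 for the loadings of Printex90 and G1-1. It was 116 for mean overload, 10 for mean non-overload and 13 for Printex90 minus titanium dioxides there. It was 7 for G1-1 minus G3-1 and 87 for G1-1 minus Bayertitan there. With the fibroblast marker covariate the count was 4 and 1 for non-overload with Printex90 and Bayertitan and 140 for Printex90 between loadings. With the epithelial marker covariate the count was 563, 1120 and 0 for overload with Printex90, G1-1 and Bayertitan, 30 and 2 for non-overload with G1-1 and G3-1 and 68 for Printex90 between loadings. It was 1626 for mean overload and 144 for G1-1 minus Bayertitan there. With both marker covariates the count was 599, 1910, 37 and 0 for overload with Printex90, G1-1, G3-1 and Bayertitan, 12, 156 and 7 for non-overload with Printex90, G1-1 and G3-1 and 80, 709 and 6 for the loadings of Printex90, G1-1 and G3-1. It was 2129 for mean overload, 879 for mean non-overload and 64 for Printex90 minus titanium dioxides there. It was 273 for G1-1 minus G3-1 and 294 for G1-1 minus Bayertitan there. Without the 15 libraries with fibroblast signal the count was 53, 139, 0 and 0 for overload with Printex90, G1-1, G3-1 and Bayertitan, 1 and 0 for non-overload with Printex90 and G1-1 and 13 and 36 for the loadings of Printex90 and G1-1. It was 1110 for mean overload, 1 for mean non-overload and 12 for Printex90 minus titanium dioxides there. It was 0 for G1-1 minus G3-1, 7 for G1-1 minus Bayertitan and 41 for the control groups there. Against G1-1 alone the Printex90 difference had 141 genes, and against G3-1 alone 21. Of the gene list tests 26 passed by fry, 121 by camera with a preset and 9 with an estimated correlation, and 41 by fry with both marker covariates.

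The replicate numbers shared by the groups of a particle were checked for pairing. Of 36 same-number pairs of libraries 15 had a correlation of deviations above 0.1 (range -0.67 to 0.43, median 0.067 against -0.051 for other pairs). Of 36 libraries 14 correlated best with their own number, so the numbers are not read as pairs. With the replicate number as a block the count was 1, 14, 8 and 1 for non-overload with Printex90, G1-1, G3-1 and Bayertitan, 500 for Printex90 between loadings and 19 for G1-1 minus G3-1, and 38 list tests passed by fry. The block left the other 12 counts within 1.5 times.

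Leaving out 1 library at a time gave counts from 0 to 88 for Bayertitan non-overload, 0 to 2319 for Bayertitan overload, 0 to 0 for Bayertitan between loadings and 312 to 954 for the control groups. They ran from 0 to 10 for G1-1 non-overload, 169 to 1157 for G1-1 minus Bayertitan, 8 to 59 for G1-1 minus G3-1 and 345 to 627 for G1-1 overload. They ran from 69 to 246 for G1-1 between loadings, 0 to 0 for G3-1 non-overload, 0 to 3 for G3-1 minus Bayertitan and 1 to 60 for G3-1 overload. They ran from 0 to 26 for G3-1 between loadings, 147 to 1338 for mean non-overload, 2697 to 3991 for mean overload and 0 to 0 for Printex90 non-overload. They ran from 18 to 38 for Printex90 minus titanium dioxides, 178 to 2234 for Printex90 overload and 11 to 1078 for Printex90 between loadings.

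Among the genes named here the sign of a log2 change turned in these cases, none of which had passed the test in either fit. Cyp1b1 in G1-1 overload went from 0.16 to -0.0043 with the replicate block, -0.26 with the fibroblast covariate, -0.39 with both covariates, -0.61 with no fibroblast-signal libraries and -0.081 without G1-1 control replicate 2. Cyp1a1 in G3-1 overload went from -0.53 to 0.44 with no fibroblast-signal libraries. Cyp1b1 in G3-1 overload went from 0.72 to -0.020 with the fibroblast covariate and -0.41 with no fibroblast-signal libraries. Cyp1a1 in Bayertitan overload went from -0.21 to 0.27 with the epithelial covariate, 0.30 with both covariates, 0.056 with no fibroblast-signal libraries and 0.056 without Bayertitan control replicate 3. Cyp1b1 in Bayertitan overload went from -0.12 to 0.20 with both covariates and 0.028 without Bayertitan control replicate 3. Ccl2 in mean overload went from 0.049 to -0.013 without G1-1 overload replicate 1. Cxcl2 in mean overload went from -0.092 to 0.0018 with the epithelial covariate. Mki67 in mean overload went from 0.12 to -0.047 with no fibroblast-signal libraries. Spp1 in mean overload went from 0.099 to -0.0019 with both covariates. Padi4 in mean overload went from -0.34 to 0.053 with the epithelial covariate and 0.0044 with both covariates. The cause was not tested.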

Other observations

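The tests of fibroblast content, with the fit without fibroblast signal, of a macrophage response in Bayertitan and of its non-overload libraries, and the regroupings of the 8 comparisons with controls, were chosen only after the result was seen. Genes that set Printex90 apart were also compared over its 2 loadings, and they were chosen after their values were seen. The scavenger receptor gene Stab1 was at 16.3 ± 3.41, 8.67 ± 1.61 and 2.94 ± 0.602 CPM in control, non-overload and overload libraries (SD, n = 3), and the apolipoprotein gene Apol3 at 8.63 ± 0.267, 4.68 ± 0.557 and 1.91 ± 0.551. The flagellin receptor gene Tlr5 was at 16.2 ± 0.629, 9.46 ± 0.841 and 5.08 ± 1.07 and the leukotriene pathway gene Alox5 at 12.8 ± 0.935, 9.18 ± 1.15 and 5.23 ± 0.731. By edgeR the step from non-overload to overload passed for these 4 genes (adjusted p = 0.0101, 0.00218, 0.00724 and 0.00265), while no step from control to non-overload passed. In the mean over particles, of 16 heat shock genes 7 were lower and 1 higher (Dnaja1, Hsp90ab1, Hspa4, Chordc1, Ahsa1, Stip1, Cryab lower, Hspb1 higher), though the list did not pass (fry adjusted p = 0.0592).

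The third pattern was the set of changed genes in Bayertitan overload, where the epithelial marker mean was -0.79 against the controls. A lower epithelial content of the overload libraries may account for much of it, since 94.2% of the 1426 changed genes moved as their slope on that mean in the 27 libraries of the other particles predicts, against 74.2% of all genes (in G1-1 53.8% against 49.0%, in Printex90 87.0% against 66.4% and in G3-1 88.2% against 61.7%). With the epithelial covariate 0 genes passed by edgeR. For the changed genes the median absolute log2 fold change went from 0.39 (median SE 0.11) to 0.26 (median SE 0.096). With the sign kept in 100%, the fold was smaller and the error no larger, for reasons not tested. Different fibroblast content is argued against as the whole cause. Its marker mean differed by 0.20, so the covariate, with which 100% of the changed genes passed, tests little. In the 2 control and 2 overload libraries without fibroblast signal 0 passed, but 100% kept the sign. Their median absolute log2 change was 0.35 (median SE 0.13). A response of the macrophages to Bayertitan cannot be told apart from lower epithelial content for these genes, because both move together within 3 libraries against 3, and non-overload does not separate them either: there, against the same controls, the epithelial marker mean was -0.69, the same genes had a median change of 0.24 in their overload direction, and 0 genes passed.

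Other splits of the same libraries were counted. For the 12 comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 1158 and 0 for Printex90, 727 and 0 for G1-1, 17 and 365 for G3-1 and 1426 and 1 for Bayertitan overload. They were 0 and 0, 9 and 0, 0 and 1 and 0 and 0 for non-overload in that order. Between the loadings they were 230 and 0, 282 and 18, 0 and 1 and 0 and 0. For G3-1 overload 2 of the 10 splits gave as many genes, and the 365 of one of them points to a structure of the samples. Control replicate 3 and overload replicates 2 and 3 of G3-1 had fibroblast signal, and the other libraries of this comparison had none. A split by that signal is thus among the 10, but which split gave the 365 is not given here. Among 100 drawn regroupings chance can be excluded for the mean overload effect (3484 and 806), the mean non-overload effect (399 and 22) and the control groups (810 and 58). It cannot for G3-1 against Bayertitan (0 and 883), where all 100 gave as many as 0. By the limit of such regroupings given above, no structure of the samples is read from the 883.

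In a principal component analysis of the 1000 most variable genes the first component held 48.9% and the second 5.24% of the variance. On the first, the 15 libraries with fibroblast signal lay at -8.33 to 67.4 and the 21 without at -31.7 to -22.1. It thus separated them by that signal.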
